A study of Homo sapiens with 63 samples.

How the data were processed

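RNA was measured in HEK293T cells, an established human embryonic kidney line, that expressed the Halo protein tag. Per the labels, cells received a Halo-binding light-releasable precursor of ibufenac or ibuprofen acyl glucuronide at 10 µM for 2 h, then washes and light for 3 min at 365 nm and 5 mW/cm2. The 63 libraries fall into 7 arms of 9 libraries: DMSO, and ibuprofen or ibufenac given as a bolus, as the photocaged form or as the probe form. Each arm was sampled at 6, 12 and 18 h with 3 replicates, which gives 21 groups. The labels do not state how the photocaged and probe forms differ, which of them received light, or the dose of the bolus. They also do not say whether replicates are separate cultures, so the p-values may measure technical spread. Libraries were made from total RNA after ribosomal RNA depletion with a stranded kit.

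The deposited expected counts, which the authors estimated for 58336 Ensembl genes without normalization, were the only values analysed. Of the values of 1 or more, 22.6% are not whole numbers, and they were rounded for the count models. The aligner, the counting program, the counting strand and the genome build are not given in the sources used here. A matching table of FPKM, a length-scaled unit, was not used because count models need counts. Current symbols matched 57754 genes, GENCODE release 29 named 462 more, and 120 had no name. Coordinates are those of GENCODE on GRCh38. All 58336 entries were genes and all 63 columns belonged to the study.

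Library totals ran from 12.1 to 38.4 M counts, with a median of 19.6 M. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 19352 tested genes. In R 4.3.3, edgeR 4.0.16 fitted a quasi-likelihood model with TMM factors (0.91 to 1.11) over the 21 groups, with 42 residual degrees of freedom, 8.2 prior degrees of freedom and a biological coefficient of variation of 0.159. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at 0.05. A gene is said to rise, fall or differ only where it passed that threshold. Fold changes are log2 values with the standard error and cover 9 libraries per arm where averaged over the 3 times, and 3 at one time. Intervals are 95%.

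In all, 39 comparisons were fitted: 11 averaged over the times, 27 at single times, and the treatment by time interaction with 12 degrees of freedom. Each of the 6 drug arms was compared with DMSO, ibufenac was compared with ibuprofen within each form, and the probe form with the photocaged form within each drug. For the drug pair, the intervals of the differences at matched times are given.

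Written gene lists, 29 in number, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The lists covered NRF2, HSF1, ATF4, p53, AhR and hypoxia targets, the unfolded protein response of the endoplasmic reticulum, immediate early, NF-kB and interferon genes, and apoptosis regulators. Metabolic lists held cholesterol and fatty acid synthesis, PPAR targets with fatty acid oxidation, prostaglandin synthesis, xenobiotic metabolism, glycolysis, nuclear and mitochondrial genes of oxidative phosphorylation, and metallothioneins. The others held ribosomal proteins, histones, G1/S and G2/M genes, abundant noncoding RNAs, and markers of hepatocytes, blood cells, epithelium and fibroblasts. The 25 lists with at least 5 tested members gave 275 tests, adjusted together. Members were also counted as called over all tested genes and with p-values adjusted over the list alone. A list score is the mean log2 CPM of its members (prior count 2). Score differences between 2 arms have exact permutation p-values over 8000 splits within times, of which 0.00025 is the smallest possible. Differences of 2 or 4 arms together from DMSO used 592704 or 94196375 splits, so their p-values can be smaller. The scores were added after the data were seen, and their p-values were not adjusted for the number of lists and comparisons.

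Named genes followed a rule. It took up to 8 higher and 8 lower called genes with the largest change in each DMSO comparison, and 6 and 6 in the others, with a mean of at least 1 CPM and the same sign at all times. It added up to 4 members of each list that passed camera, 12 fixed genes, and 6 genes of the interaction. Names from the lower end were left out of the text. The comparisons, tests, lists, this rule, and the alternatives of DESeq2, RLE factors, no low-count filter, a replicate block and leaving out each library were chosen before the data were examined. Removing GC and length trends, and leaving out the libraries that stand apart, were chosen after seeing the data, as were 5 further lists.

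Among the 63 pairs of libraries within groups none were duplicates. In tests on simulated data for the ibufenac photocaged arm, 56% of genes with a planted 1.25-fold change, 94% at 1.5-fold and 100% at 2-fold were found over the 3 times, with 10 false calls among 19022 genes. At 6 h alone these were 32%, 68% and 94%, with 7 false calls. The simulated genes varied independently, with no structure shared within a library, so these shares and false calls may not hold for the real libraries. DESeq2 was version 1.42.0.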

Results

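Transcripts were measured in HEK293T cells carrying a Halo tag after treatment with ibuprofen or with ibufenac, a closely related drug that lacks ibuprofen's α-methyl group. Both drugs can form reactive acyl glucuronides, and the photocaged precursors were built to release these inside cells when lit. Each of the 7 arms had 3 libraries at 6 h, 12 h and 18 h, for 63 libraries with 12.1 to 38.4 M counts each (median 19.6 M). Protein-coding genes took 68.4% to 83.3% of the counts. Over the whole design, PTGS1 and PTGS2, the cyclooxygenases that both drugs inhibit, stayed at or below 27 and 64 counts in any library, and neither was called in any averaged comparison.

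Both arms labelled as bolus, whose dose the labels do not give, were compared with DMSO over the 3 times. Few genes were called. With ibuprofen, SLC16A9, a carrier of the monocarboxylate family, rose (0.69 ± 0.12, adjusted p = 0.0116, n = 9 libraries per arm, edgeR). CPT1A, which carries fatty acids into mitochondria for oxidation, rose by a smaller amount (0.30 ± 0.06, adjusted p = 0.0254). With ibufenac, the transcription factor ZNF143 fell (-0.48 ± 0.08, adjusted p = 0.000567), as did the zinc importer SLC39A10 (-0.40 ± 0.06, adjusted p = 0.000269). ZNF143 also fell with ibuprofen (-0.37 ± 0.07, adjusted p = 0.0398).

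In total, edgeR called 5 genes for the ibuprofen bolus (4 higher, 1 lower) and 2 for the ibufenac bolus (both lower), where 2035 and 1688 genes had an unadjusted p under 0.05 and DESeq2 called 38 and 26. The ibuprofen calls were fragile: leaving out one library gave from 0 calls (without DMSO 12 h replicate 3, DMSO 18 h replicate 3 or ibuprofen bolus 18 h replicate 3) to 76 (without ibuprofen bolus 12 h replicate 1). The SLC16A9 call ended without those same first 3 libraries, although its change stayed at 0.67, 0.68 and 0.67. Both ibufenac calls passed in every alternative fitted to all arms, whereas a fit of the 18 libraries of these arms alone called 0 genes. At single times the ibuprofen bolus gave 0, 2 and 14 calls at 6, 12 and 18 h (at 6 h, 2134 genes had an unadjusted p under 0.05 and DESeq2 called 2). The ibufenac bolus gave 5, 0 and 973 (at 12 h, 695 had an unadjusted p under 0.05 and DESeq2 called 6). The count of 973 fell to 54 without ibufenac bolus 18 h replicate 3, one of the 2 libraries that stand apart from their groups. No list kept its preset camera call with an estimated correlation in either bolus arm. The NRF2 and ATF4 scores moved by 0.01, 95% interval -0.05 to 0.08 and 0.02, 95% interval -0.03 to 0.08 with ibuprofen. With ibufenac they moved by 0.00, 95% interval -0.06 to 0.07 and -0.01, 95% interval -0.07 to 0.04. The hypoxia and glycolysis scores moved by -0.01 (-0.16 to 0.14) and -0.07 (-0.16 to 0.03) with ibuprofen. With ibufenac they moved by -0.13 (-0.285 to 0.02) and -0.11 (-0.20 to -0.01), exact permutation p = 0.285 and 0.0552. No member of these 2 lists was called there, but 2 and 3 fell when adjusted over the list alone. A small fall with the ibufenac bolus is therefore not excluded.

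To determine what the photocaged precursors did, both photocaged arms were compared with DMSO. NRF2 and ATF4 targets rose, and hypoxia targets and glycolysis genes fell. HMOX1, the heme-degrading enzyme on chromosome 22 (35380361 to 35394214, GRCh38), was at 25.7 ± 1.2 CPM (SD, n = 3) in DMSO at 6 h. It reached 59.9 ± 7.8 with photocaged ibuprofen and 66 ± 11 with photocaged ibufenac. These were log2 changes of 1.22 ± 0.15, adjusted p = 2.77e-07 and 1.36 ± 0.15, adjusted p = 7.19e-09 (edgeR). At 18 h HMOX1 did not pass with either drug (-0.07 ± 0.15, adjusted p = 0.87, and 0.14 ± 0.15, adjusted p = 0.674). The retinoic acid receptor gene RARB (chromosome 3, 25174332 to 25597932) fell over the 3 times (-1.18 ± 0.14, adjusted p = 6.52e-08 with ibuprofen, and -1.55 ± 0.14, adjusted p = 2.42e-11 with ibufenac). Its level at 12 h was 12.2 ± 0.78 CPM in DMSO, 5.3 ± 0.49 with ibuprofen and 3.45 ± 0.82 with ibufenac (SD, n = 3).

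**Figure D1:**
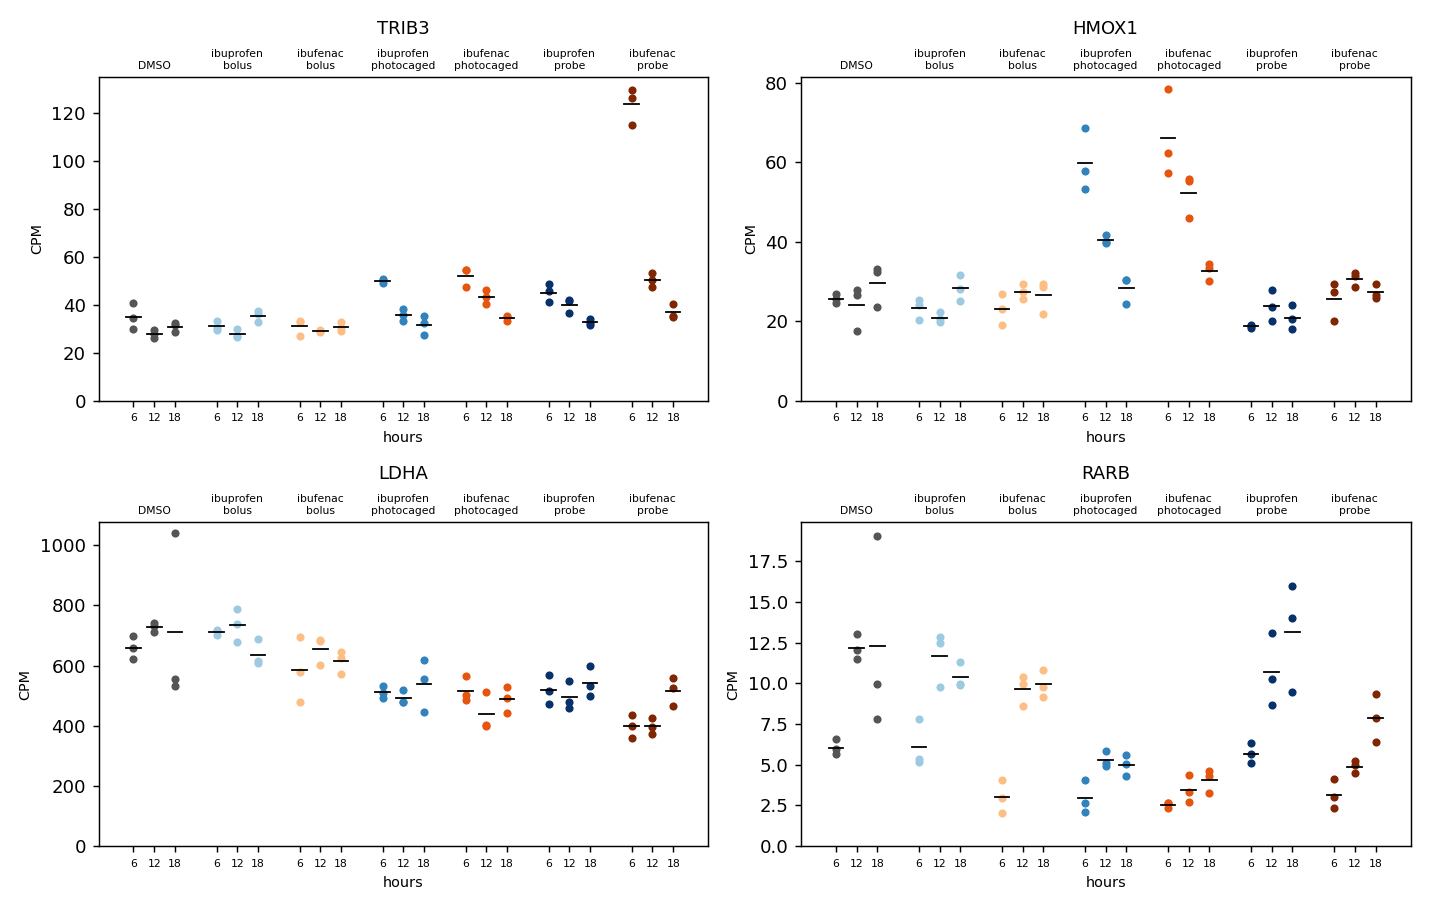
CPM of TRIB3, HMOX1, LDHA and RARB (y axes) at 6, 12 and 18 h (x axes) in each arm; each point is a library and each bar is the mean of 3. HMOX1 at 6 h lies at 59.9 and 66 CPM in the photocaged arms against 25.7 in DMSO, and TRIB3 at 124 CPM with the ibufenac probe against 35.1.

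Of 24 tested NRF2 targets, the antioxidant and thiol genes, 7 rose and none fell with photocaged ibuprofen (12 rose when adjusted over the list alone), and 12 rose and none fell with photocaged ibufenac (14 rose and 1 fell when adjusted over the list alone). TXNRD1, the cytosolic thioredoxin reductase, rose with both drugs (0.32 ± 0.04 and 0.56 ± 0.04, adjusted p = 1.05e-16). So did GCLM, a subunit of the enzyme that limits glutathione synthesis (0.51 ± 0.06 and 0.64 ± 0.06). SLC7A11, the cystine importer, rose as well (0.33 ± 0.06 and 0.60 ± 0.06), but it also belongs to the ATF4 list and does not point to NRF2 alone. The list score was higher by 0.23, 95% interval 0.17 to 0.29, exact permutation p = 5e-04, and by 0.31, 95% interval 0.24 to 0.37, exact permutation p = 0.00025, in the ibuprofen and ibufenac arms. At 6, 12 and 18 h it was higher by 0.24, 0.23 and 0.21 for ibuprofen and by 0.29, 0.34 and 0.29 for ibufenac. The 18 h values are set against low controls. DMSO libraries scored 4.55, 4.82 and 4.65 there, and the ibuprofen bolus 4.83, 4.72 and 4.81. The ibufenac bolus scored 4.82, 4.70 and 4.73, so part of the 18 h difference may not be particular to the photocaged arms. With 6 and 12 h alone the differences were 0.24 and 0.32.

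The ATF4 list, genes of the integrated stress response, also rose. With ibuprofen 8 of 25 members rose and 1 fell (13 and 3 adjusted over the list alone), and with ibufenac 14 rose and 1 fell (16 and 2 adjusted over the list alone). ASNS, which makes asparagine, rose (0.39 ± 0.04, adjusted p = 1.48e-08, and 0.56 ± 0.04, adjusted p = 5.59e-15). TRIB3, a pseudokinase induced by ATF4, rose less (0.30 ± 0.05 and 0.46 ± 0.05). The stress-induced regulator NUPR1, a member too, rose with ibufenac (1.16 ± 0.16). The list score fell back over time, from 0.34, 0.25 to 0.43 at 6 h to -0.03, -0.12 to 0.07 at 18 h for ibuprofen. For ibufenac it went from 0.50, 0.41 to 0.60 to 0.00, -0.10 to 0.09. Genes of the unfolded protein response rose with photocaged ibufenac, 12 of 20 (13 adjusted over the list alone), among them the transcription factor XBP1 (0.54 ± 0.04, adjusted p = 1.48e-15) and the chaperone partner DNAJB9 (0.39 ± 0.08). With photocaged ibuprofen 2 of 20 rose (3 adjusted over the list alone), and that list had adjusted p = 0.0602 with an estimated correlation.

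Hypoxia targets and glycolysis genes were lower. Of 23 hypoxia targets 16 fell with ibuprofen and 19 with ibufenac (20 each adjusted over the list alone), and none rose. Of 17 glycolysis genes 9 and 12 fell (14 and 13 adjusted over the list alone). HK2, LDHA, ENO2 and PGK1 belong to both lists, so the results overlap. LDHA, which turns pyruvate into lactate, fell (-0.44 ± 0.08, adjusted p = 0.000304, and -0.54 ± 0.08, adjusted p = 3.62e-06), with 728 ± 16 CPM in DMSO at 12 h against 493 ± 23 and 437 ± 65 (SD, n = 3). PGK1, a glycolytic kinase, fell too (-0.38 ± 0.07 and -0.41 ± 0.07), as did the mitophagy gene BNIP3 with ibufenac (-0.73 ± 0.11). The hypoxia score differed by -0.36, 95% interval -0.52 to -0.21, exact permutation p = 0.0015 with ibuprofen and by -0.42, 95% interval -0.57 to -0.27, exact permutation p = 0.00025 with ibufenac, and 1 control library mattered most: without DMSO 18 h replicate 3 the differences were -0.27 and -0.33. With 6 and 12 h alone they were -0.38 and -0.41. At 18 h DMSO replicate 3 scored 6.05 and the other DMSO libraries 5.16 and 5.20. Photocaged ibuprofen scored 5.24, 4.97 and 5.21 there, so its fall at 18 h rests largely on that replicate. Photocaged ibufenac scored 4.99, 4.93 and 5.14.

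Outside the lists, GNG2, a G protein subunit, rose most among the genes named for both arms (1.41 ± 0.25, adjusted p = 0.000304, and 1.54 ± 0.25, adjusted p = 2.85e-05). The cell adhesion gene CDH3 rose (1.18 ± 0.26 and 1.23 ± 0.26). Photocaged ibufenac also raised SLC16A9 (1.03 ± 0.12) and lowered the chemokine receptor CXCR4 (-1.01 ± 0.15). MIR210HG, the host transcript of a hypoxia-induced microRNA, fell in both arms (-1.51 ± 0.30 and -1.69 ± 0.30). With photocaged ibuprofen the prostaglandin receptor gene PTGER3 rose (1.16 ± 0.26) and CITED2, a regulator of hypoxic transcription, fell (-0.82 ± 0.14).

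Counts of called genes were 829 for photocaged ibuprofen (384 higher, 445 lower) and 1450 for photocaged ibufenac (799 higher, 651 lower). Of these, 82 and 159 changed over 1.5-fold. The first count was 533 without DMSO 12 h replicate 1. At 6, 12 and 18 h there were 192, 131 and 428 calls for ibuprofen and 587, 306 and 553 for ibufenac. Fits of the 6 libraries alone gave 137, 729 and 0 and then 66, 1686 and 1, so counts at one time depend on which libraries set the spread. With the preset correlation 12 and 11 of 25 lists passed camera. Of these NRF2, ATF4, AhR, hypoxia and glycolysis kept their calls with an estimated correlation in both arms, as did the unfolded protein response with ibufenac. In the AhR list, genes of the dioxin receptor, 2 of 7 rose in each arm (4 adjusted over the list alone), including the enzyme gene TIPARP with ibufenac (0.28 ± 0.05). Its score rose by 0.29, 95% interval 0.12 to 0.47, exact permutation p = 0.003, and by 0.36, 95% interval 0.18 to 0.54, exact permutation p = 0.0055. The differences were 0.04 (-0.26 to 0.35), 0.42 and 0.42 at 6, 12 and 18 h with ibuprofen and 0.02 (-0.28 to 0.33), 0.32 and 0.73 with ibufenac. At 18 h the ibuprofen bolus lay above DMSO as well, by 0.50 (0.19 to 0.80), so that time does not set photocaged ibuprofen apart. The ibufenac bolus scored 2.155, 1.65 and 1.77 there, against 1.62, 2.20 and 1.67 in DMSO and 2.37, 2.86 and 2.46 with photocaged ibufenac.

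Of the other lists with a preset call, HSF1 heat shock genes fell in 5 of 18 members in each arm (7 and 6 adjusted over the list alone), with adjusted p = 0.0597 with an estimated correlation for ibuprofen and adjusted p = 0.378 with an estimated correlation for ibufenac. Members of the p53 list rose, 6 and 5 of 22 (9 and 7 adjusted over the list alone) with the death receptor gene FAS among them (0.40 ± 0.07 and 0.39 ± 0.07), and the list had adjusted p = 0.0689 with an estimated correlation and adjusted p = 0.378 with an estimated correlation. Cholesterol synthesis genes fell in 5 and 8 of 25 (7 and 11 adjusted over the list alone), SQLE included (-0.20 ± 0.05 and -0.25 ± 0.05), with adjusted p = 0.262 with an estimated correlation and adjusted p = 0.102 with an estimated correlation. Histone genes had adjusted p = 0.619 with an estimated correlation and adjusted p = 0.707 with an estimated correlation. Interferon genes and G1/S genes passed only for ibuprofen, with adjusted p = 0.244 with an estimated correlation and adjusted p = 0.0726 with an estimated correlation, and nuclear oxidative phosphorylation genes only for ibufenac, with adjusted p = 0.472 with an estimated correlation.

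**Figure D2:**
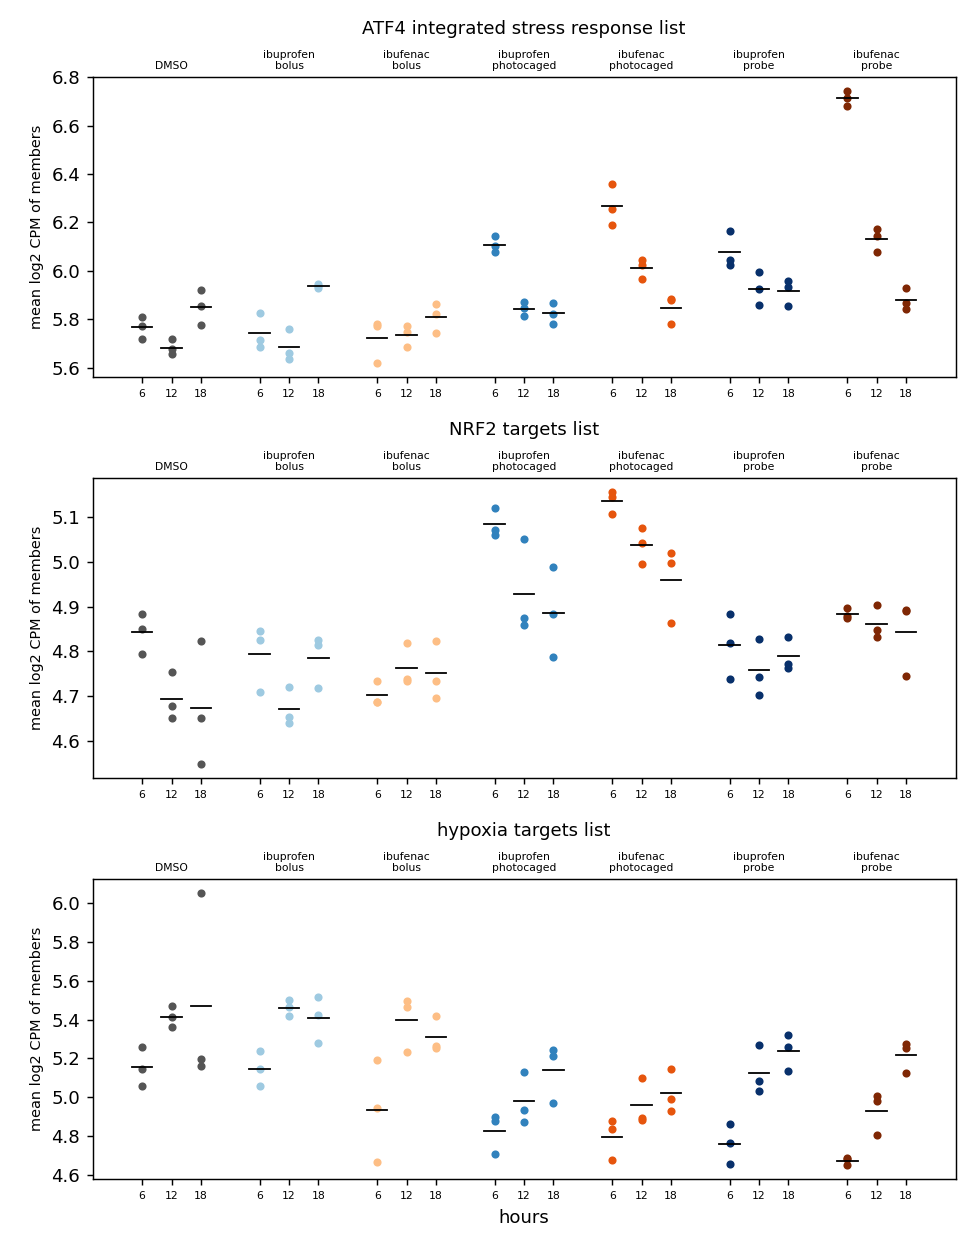
Scores of the ATF4, NRF2 and hypoxia lists (y axes, mean log2 CPM of list members) at 6, 12 and 18 h (x axes) in each arm; each point is a library and each bar is the mean of 3. The highest ATF4 scores are those of the ibufenac probe at 6 h, the NRF2 scores are highest in the photocaged arms at 6 h, and 1 DMSO library at 18 h stands far above the others in the hypoxia list.

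The same comparison for the probe form asked whether its effects were alike. ATF4 targets rose again, heat shock genes fell, and NRF2 targets as a list did not pass camera. With the ibufenac probe at 6 h TRIB3 (chromosome 20, 362835 to 397559) stood at 124 ± 7.6 CPM against 35.1 ± 5.5 in DMSO (SD, n = 3), a log2 change of 1.82 ± 0.09, adjusted p = 1.56e-20 (edgeR). It was 0.86 ± 0.09, adjusted p = 1.28e-08 at 12 h and 0.26 ± 0.10, adjusted p = 0.135 at 18 h, where it did not pass. ASNS (chromosome 7, 97852118 to 97872542) rose over the 3 times with both probes (0.58 ± 0.04, adjusted p = 5.32e-15, and 0.88 ± 0.04, adjusted p = 1.06e-22). DDIT3, the stress factor CHOP, rose at 6 h with the ibufenac probe (1.06 ± 0.12, adjusted p = 5.98e-09) but not with the ibuprofen probe (0.07 ± 0.12, adjusted p = 0.782). GDF15, a secreted stress signal, did the same at 6 h (1.78 ± 0.28, adjusted p = 7.91e-06, and -0.04 ± 0.30, adjusted p = 0.963).

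Of 25 ATF4 targets 12 rose and 1 fell with the ibuprofen probe (14 and 1 adjusted over the list alone), and 17 rose and none fell with the ibufenac probe (20 adjusted over the list alone). The score rose by 0.21, 95% interval 0.15 to 0.26, exact permutation p = 5e-04, and by 0.47, 95% interval 0.42 to 0.53, exact permutation p = 0.0015. At 6, 12 and 18 h it differed by 0.31, 0.24 and 0.06 (95% interval at 18 h -0.03 to 0.16) with ibuprofen and by 0.95, 0.45 and 0.03 (-0.07 to 0.12) with ibufenac. SLC7A11 rose with both (0.49 ± 0.06 and 0.68 ± 0.06), as did the serine synthesis gene PSAT1 with ibuprofen (0.43 ± 0.05) and the one-carbon gene MTHFD2 with ibufenac (0.49 ± 0.04). Removing GC and length trends raised the TRIB3 change with the ibuprofen probe from 0.32 ± 0.05 to 0.51. Unfolded protein response genes rose with the ibufenac probe, 10 of 20 (11 adjusted over the list alone), among them XBP1 (0.63 ± 0.04) and the chaperone HSPA5 (0.39 ± 0.08). With the ibuprofen probe 1 of 20 rose (1 rose and 1 fell adjusted over the list alone), and the score difference was -0.02, 95% interval -0.05 to 0.02.

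Heat shock genes fell in 13 of 18 members with each probe (15 each adjusted over the list alone, with 1 higher for ibuprofen). HSPE1, a mitochondrial chaperonin, fell (-0.30 ± 0.06 and -0.57 ± 0.06), as did the co-chaperone STIP1 (-0.28 ± 0.04 and -0.33 ± 0.04). HSPA1B, an inducible HSP70 gene, fell by 0.96 on the log2 scale with the ibuprofen probe, although its reads can be shared with the paralog HSPA1A. The score fell by -0.28, 95% interval -0.37 to -0.20, exact permutation p = 0.00025, and by -0.35, 95% interval -0.43 to -0.27, exact permutation p = 0.0015. At 6, 12 and 18 h it differed by -0.47, -0.19 and -0.20 (95% interval at 18 h -0.34 to -0.05) with ibuprofen. With ibufenac the values were -0.52, -0.47 and -0.06, and the interval at 18 h (-0.20 to 0.09) spanned 0.

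Of 24 NRF2 targets, 2 rose and 2 fell with the ibuprofen probe (4 and 2 adjusted over the list alone), and 7 rose and 3 fell with the ibufenac probe (the same numbers adjusted over the list alone). Camera did not pass at the preset correlation (adjusted p = 0.332, and adjusted p = 0.0955). The score was nevertheless higher with the ibufenac probe, by 0.13, 95% interval 0.06 to 0.19, exact permutation p = 0.004, unadjusted for the number of lists. It was higher by 0.04 at 6 h and by 0.17 (0.06 to 0.28) at both 12 and 18 h. The low DMSO scores at 18 h apply here too, and with 6 and 12 h alone the difference was 0.10 (0.03 to 0.18). With the ibuprofen probe the score gave 0.05, 95% interval -0.01 to 0.11, exact permutation p = 0.204. GCLM rose (0.26 ± 0.06 and 0.22 ± 0.06). HMOX1 fell with the ibuprofen probe (-0.32 ± 0.09, adjusted p = 0.014), a call that ended without DMSO 12 h replicate 1 (-0.28) and with GC and length trends removed (-0.16). With the ibufenac probe HMOX1 did not pass (0.08 ± 0.09, adjusted p = 0.652).

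Hypoxia targets fell in 14 and 16 of 23 (18 and 20 adjusted over the list alone), with adjusted p = 0.0958 with an estimated correlation and adjusted p = 0.0665 with an estimated correlation. Glycolysis genes fell in 11 of 17 with each probe (11 and 13 adjusted over the list alone). LDHA fell (-0.43 ± 0.08, and -0.69 ± 0.08, adjusted p = 4.71e-09), and so did the pyruvate kinase gene PKM (-0.28 ± 0.04 and -0.42 ± 0.04). Without DMSO 18 h replicate 3 the hypoxia score differences went from -0.30 to -0.21 for ibuprofen and from -0.41 to -0.31 for ibufenac. With 6 and 12 h alone they were -0.34 and -0.48. At 18 h the other DMSO libraries scored 5.16 and 5.20. The ibuprofen probe scored 5.32, 5.13 and 5.26 there and the ibufenac probe 5.12, 5.25 and 5.28, so a fall at 18 h rests on that replicate. GNG2 had the largest rise among the genes named for the ibufenac probe (2.09 ± 0.25, adjusted p = 1.17e-08), followed by DCT, a melanin pathway enzyme (1.80 ± 0.24), and it rose with ibuprofen (1.34 ± 0.25). The ibufenac probe lowered the secreted hormone gene STC1 (-1.97 ± 0.43) and CXCR4 (-1.26 ± 0.16), and the ibuprofen probe lowered the immediate early genes ARC (-1.38 ± 0.28) and FOS (-0.84 ± 0.19).

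The ibuprofen probe gave 1631 calls (738 higher, 893 lower), of which 173 were over 1.5-fold, and 1005 without DMSO 12 h replicate 1. The ibufenac probe gave 2549 (1135 higher, 1414 lower), of which 376 were over 1.5-fold. At 6, 12 and 18 h there were 2213, 381 and 344 calls for ibuprofen and 2466, 872 and 521 for ibufenac, while fits of the 6 libraries alone gave 2352, 2108 and 282 and then 2228, 191 and 6. The first of these counts ran from 424, without ibuprofen probe 6 h replicate 2, to 2481, and the ibufenac count at 6 h was 1493 without DMSO 6 h replicate 1. Camera passed 9 and 11 lists at the preset correlation. ATF4, HSF1 and glycolysis held with an estimated correlation in both arms, and the unfolded protein response in the ibufenac arm.

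Among lists that lost their call, NF-kB genes rose in 1 and 4 of 15 members with the probes, by either count (adjusted p = 0.213 with an estimated correlation, and adjusted p = 0.0655 with an estimated correlation), with the neutrophil chemokine CXCL8 among the called members (0.81 ± 0.20 and 0.91 ± 0.21). Immediate early, p53 and G1/S genes had adjusted p = 0.134 with an estimated correlation, adjusted p = 0.469 with an estimated correlation and adjusted p = 0.12 with an estimated correlation for ibuprofen. Cholesterol and G2/M genes had adjusted p = 0.0974 with an estimated correlation and adjusted p = 0.168 with an estimated correlation for ibufenac, where 10 of 25 and 7 of 26 fell (13 and 10 adjusted over the list alone). Nuclear oxidative phosphorylation genes and ribosomal protein genes had adjusted p = 0.489 with an estimated correlation and adjusted p = 0.489 with an estimated correlation for ibufenac. Histone genes had adjusted p = 0.472 with an estimated correlation and adjusted p = 0.707 with an estimated correlation.

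Lists of fatty acid synthesis, PPAR targets, prostaglandin synthesis, xenobiotic metabolism, apoptosis regulators, abundant noncoding RNAs and fibroblast markers passed camera in none of the 6 DMSO comparisons. For the ibufenac probe their preset values were adjusted p = 0.111 for fatty acid synthesis, adjusted p = 0.701 for PPAR targets, adjusted p = 0.482 for prostaglandin synthesis and adjusted p = 0.563 for xenobiotic metabolism. Apoptosis regulators had adjusted p = 0.302, noncoding RNAs adjusted p = 0.136 and fibroblast markers adjusted p = 0.154. Mitochondrial mRNAs passed only in the bolus arms, with adjusted p = 0.508 with an estimated correlation for ibuprofen and adjusted p = 0.558 with an estimated correlation for ibufenac. Metallothionein, hepatocyte, blood cell and epithelial marker lists had 4 tested genes each and were not tested as sets. Their highest mean levels were 43.1, 57.5, 1.86 and 2.13 CPM.

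**Figure D3:**
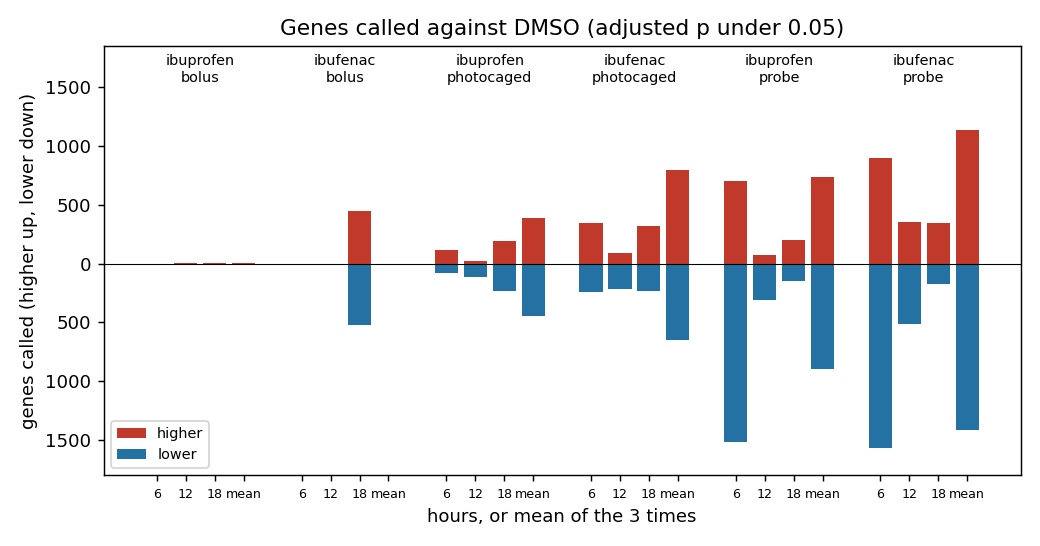
Number of genes called higher (above 0) and lower (below 0) against DMSO (y axis, adjusted p under 0.05 in edgeR) at 6, 12 and 18 h and for the mean of the 3 times (x axis) in the 6 drug arms. For the mean the bolus arms show 5 and 2 genes against 829 to 2549 in the photocaged and probe arms.

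Because all arms share the same DMSO libraries, overlaps between arms were measured with that sharing in view. The photocaged arms of the 2 drugs shared 297 higher and 327 lower genes and none in opposite directions, where independent lists would share 15.9 and 15. When each drug was compared with different DMSO libraries, 3 for one and 6 for the other, they still shared 52 higher and 46 lower genes, or 63 and 79 with the controls exchanged. The probe arms shared 467 and 452 genes, and 122 and 86 or 170 and 174 with separate controls. With separate, and so fewer, controls, fold changes correlated at 0.187 and 0.19 in the photocaged arms and at 0.16 and 0.198 in the probe arms. With all controls shared they correlated at 0.598 in the photocaged arms and 0.557 in the probe arms. The value was 0.507 in simulated arms with no change but the same controls. Fewer controls make fold changes noisier, which by itself lowers a correlation. The covariances with all controls shared were 0.113 and 0.118, against 0.0693 in the simulated arms. With separate controls they were 0.0728 and 0.0742 in the photocaged arms and 0.0671 and 0.0793 in the probe arms. The simulated arms took the library sizes of the photocaged arms only. These simulated arms shared 0 calls in 20 simulations, a count that arms without changes give in any case and that does not measure the overlap due to shared controls.

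To test whether ibufenac and ibuprofen differed, both drugs were compared at matched forms and times. In the photocaged form few genes were called. TXNRD1 was higher with ibufenac (0.23 ± 0.04, adjusted p = 0.000572), as was XBP1 (0.21 ± 0.04, adjusted p = 0.00881). The amino acid carriers SLC1A4 (0.26 ± 0.05, adjusted p = 0.0108) and SLC7A11 (0.27 ± 0.06, adjusted p = 0.0374), the one-carbon enzyme MTHFD2 (0.19 ± 0.04, adjusted p = 0.0473) and the filament gene VIM (0.16 ± 0.03, adjusted p = 0.0108) were higher, and the endocytic receptor gene LRP2 was lower (-0.43 ± 0.09, adjusted p = 0.0374). These 7 genes were all that edgeR called over the 3 times, against 921 with an unadjusted p under 0.05 and 18 in DESeq2. From 2 to 8 were called when any one library was left out. TXNRD1 and XBP1 passed in every alternative fitted to all arms. The SLC1A4 call ended without ibufenac photocaged 6 h replicate 1 or 18 h replicate 2 (0.25 and 0.24). Those of VIM, SLC7A11, LRP2 and MTHFD2 ended in 5 to 16 of the 18 fits.

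At 6, 12 and 18 h alone edgeR called 0 genes each between the photocaged drugs, with 935, 583 and 577 at an unadjusted p under 0.05 and 6, 1 and 2 in DESeq2. TRIB3 was called at no time, although its interval at 12 h lay above 0 (differences of 0.06, 95% interval -0.12 to 0.25 at 6 h, 0.28, 95% interval 0.09 to 0.47 at 12 h and 0.13, 95% interval -0.06 to 0.32 at 18 h). The same held for HMOX1 (0.14, 95% interval -0.15 to 0.43 at 6 h, 0.37, 95% interval 0.08 to 0.66 at 12 h and 0.20, 95% interval -0.09 to 0.50 at 18 h). As a list ATF4 targets were higher with ibufenac, 2 of 25 (11 adjusted over the list alone), with a score difference of 0.12, 95% interval 0.06 to 0.17, exact permutation p = 0.00175. The difference was 0.16, 0.07 to 0.25 at 6 h, 0.17, 0.08 to 0.26 at 12 h and 0.02, -0.07 to 0.12 at 18 h. Unfolded protein response genes were higher by 0.09, 95% interval 0.05 to 0.12, exact permutation p = 0.001 (1 of 20 called, 9 adjusted over the list alone) and NRF2 targets by 0.08, 95% interval 0.01 to 0.14, exact permutation p = 0.032 (2 of 24 by either count). Of 9 lists with a preset call these 3 held with an estimated correlation. The interval spanned 0 for hypoxia targets (-0.06, 95% interval -0.21 to 0.09), glycolysis genes (-0.01, 95% interval -0.11 to 0.08) and heat shock genes (0.03, 95% interval -0.05 to 0.11).

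In the probe form the drugs differed more, mostly at 6 h. TRIB3 was higher with ibufenac over the 3 times (0.65 ± 0.05, adjusted p = 2.84e-12), by 1.46 ± 0.09 at 6 h and 0.33 ± 0.09 at 12 h, while at 18 h it did not pass (0.18, 95% interval -0.01 to 0.37). DDIT3 and GDF15 were higher at 6 h (0.98 ± 0.12 and 1.82 ± 0.29), and neither passed at 18 h (-0.25, 95% interval -0.50 to -0.01 and -0.14, 95% interval -0.66 to 0.39). HSPA5 was higher (0.36 ± 0.08), and RARB was lower (-0.90 ± 0.14, adjusted p = 2.28e-05). The YAP-responsive gene ANKRD1 (1.09 ± 0.17) and the activin subunit INHBA (0.97 ± 0.16) were higher with ibufenac, and PTGER3 was lower (-1.18 ± 0.26). IDI1, an enzyme of sterol precursor synthesis, was lower (-0.37 ± 0.05, adjusted p = 5.43e-06).

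Of the ATF4 list 12 of 25 members were higher with the ibufenac probe (22 adjusted over the list alone) and none lower, with a score difference of 0.27, 95% interval 0.21 to 0.32, exact permutation p = 0.007. It was 0.63, 0.54 to 0.73 at 6 h, 0.20, 0.11 to 0.30 at 12 h and -0.04, -0.13 to 0.06 at 18 h, where the interval spanned 0. Unfolded protein response genes were higher by 0.17, 95% interval 0.13 to 0.20, exact permutation p = 0.00025 (5 of 20, 11 adjusted over the list alone). Cholesterol synthesis genes were lower by -0.16, 95% interval -0.22 to -0.10, exact permutation p = 5e-04 (11 of 25, 16 adjusted over the list alone). Of 9 lists with a preset call these 3 held with an estimated correlation. NRF2 targets did not pass camera (adjusted p = 0.342), although their score differed by 0.08, 95% interval 0.01 to 0.14, exact permutation p = 0.014. The drug difference was larger in the probe form than in the photocaged form for ATF4 (by 0.15, 95% interval 0.07 to 0.23), but not for NRF2 (0.00, -0.09 to 0.09).

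Over the 3 times 546 genes differed between the probes (219 higher with ibufenac, 327 lower). There were 4573, 372 and 0 at 6, 12 and 18 h, and at 18 h 1065 had an unadjusted p under 0.05 and DESeq2 called 11. The 12 h count ran from 83 to 867 with 1 library left out. The averaged count fell to 334 to 352 without any of ibuprofen probe 6 h replicate 1, 12 h replicate 3 or 18 h replicate 1, or ibufenac probe 18 h replicate 1. With GC and length trends removed the count at 6 h was 2534. The libraries also differed in the share of 14 abundant small noncoding RNAs at 6 h, at 25.6% ± 0.8 with ibufenac and 18.2% ± 2.5 with ibuprofen (SD, n = 3). With that share as a covariate the count was 1411.

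In bolus form edgeR called 0 genes between the drugs over the 3 times (1342 with an unadjusted p under 0.05, and 12 in DESeq2). At 6, 12 and 18 h it called 446, 7 and 0 (2502 unadjusted and 4 in DESeq2 at 18 h). The 446 became 5 without ibuprofen bolus 6 h replicate 1, 16 without its replicate 2, 206 without its replicate 3 and 29 without ibufenac bolus 6 h replicate 3. TRIB3 and HMOX1 were not called over the times (differences of -0.05, 95% interval -0.16 to 0.06 and 0.10, 95% interval -0.08 to 0.27). The ATF4 score gave an interval around 0 (-0.03, 95% interval -0.09 to 0.02). The p53 list was higher with ibufenac in camera (adjusted p = 0.0196 with an estimated correlation), but no member was called (4 adjusted over the list alone) and its score gave 0.11, 95% interval 0.03 to 0.19, exact permutation p = 0.09.

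To ask how the probe and photocaged forms differed, they were compared within each drug. HMOX1 was lower in the probe form with ibuprofen (-0.96 ± 0.09, adjusted p = 8.25e-11) and with ibufenac (-0.80 ± 0.09, adjusted p = 9.85e-09). TXNRD1 was lower too (-0.25 ± 0.04 and -0.43 ± 0.04, adjusted p = 2.17e-12), as was FTL, the ferritin light chain (-0.25 ± 0.04 and -0.30 ± 0.04). With ibufenac the antioxidant gene PRDX1 was lower (-0.32 ± 0.04), and TRIB3 was higher (0.52 ± 0.05, adjusted p = 4.13e-09). With ibuprofen RARB was higher in the probe form (1.12 ± 0.14, adjusted p = 1.11e-06), and in the probe arm it had not passed against DMSO (-0.06 ± 0.13, adjusted p = 0.851).

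NRF2 targets were lower in the probe form, 3 of 24 with ibuprofen (9 lower and 1 higher adjusted over the list alone) and 12 with ibufenac (12 adjusted over the list alone). Their scores differed by -0.18, 95% interval -0.24 to -0.12, exact permutation p = 0.00075, and by -0.18, 95% interval -0.24 to -0.12, exact permutation p = 0.00075. Heat shock genes were lower with the ibufenac probe, 10 of 18 (14 adjusted over the list alone), among them DNAJA1 (-0.40 ± 0.05) and HSPA8 (-0.29 ± 0.04), and with ibuprofen the list had adjusted p = 0.0665 with an estimated correlation. ATF4 targets were higher with the ibufenac probe, 12 of 25 (15 adjusted over the list alone), by 0.20, 95% interval 0.14 to 0.25, exact permutation p = 0.0025. With ibuprofen they had adjusted p = 0.0578 with an estimated correlation. With ibuprofen the cholesterol list was higher in the probe form, with 2 of 25 members called (7 adjusted over the list alone; 0.10, adjusted p = 0.0133 with an estimated correlation). The AhR list (-0.20, adjusted p = 0.0203 with an estimated correlation) and the xenobiotic list (-0.11, adjusted p = 0.0431 with an estimated correlation) passed camera as lower, but 0 of 7 and 0 of 15 members were called (1 and 0 adjusted over the list alone). Of 9 and 10 lists with a preset call, 4 and 3 held with an estimated correlation. In total 19 genes differed with ibuprofen (8 higher, 11 lower) and 519 with ibufenac (164 higher, 355 lower). The first count was 92 in DESeq2 and 54 with GC and length trends removed, and it was 34, 29 and 41 without ibuprofen photocaged 6 h replicate 3, probe 6 h replicate 3 or photocaged 18 h replicate 3. The second was 316 and 304 without ibufenac photocaged 6 h replicate 1 or 12 h replicate 3.

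To test whether arms changed differently over time, the treatment by time interaction was fitted. It called 4410 genes (6772 with an unadjusted p under 0.05), and 1876 with the small noncoding RNA share as a covariate. ASNS and TRIB3 had the smallest adjusted p (8.05e-14 and 1.75e-13, edgeR). The cystathionase gene CTH followed (8.55e-12), then XBP1 (1.39e-10), the scaffold gene AHNAK (1.79e-10) and CEBPG, a partner of ATF4 (1.87e-10). ASNS stood at 129 ± 4.8 CPM in DMSO at 6 h and between 220 and 304 CPM in the 4 photocaged and probe arms. At 18 h it was 125 ± 7.3 in DMSO and still higher with the ibuprofen probe (0.33 ± 0.07, adjusted p = 0.00907).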

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

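The list scores, the removal of GC and length trends, the small noncoding RNA covariate and the test of handling shared by both drugs were chosen after the data were seen; only for the last of them was the expected outcome also written after its result.

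Several results stood out because effects differed between times or forms by a test of the difference itself. The arm effects against DMSO differed between the 3 times for 4410 genes, and for 1876 with the share of abundant small noncoding RNAs as a covariate. The ibufenac minus ibuprofen difference changed over time for 3600 genes in the probe form and for 1229 in the bolus form, while in the photocaged form edgeR called 0 (553 with an unadjusted p under 0.05; DESeq2 was not run for this test). The bolus groups hold both libraries that stand apart, ibufenac bolus replicate 3 at 6 h and at 18 h. The change of the drug difference over time was not refitted with libraries left out or with the share covariate. At 6 h alone the bolus drug difference ran from 5 to 777 genes with 1 library left out, so the 1229 may reflect single libraries. The drug difference itself differed between probe and photocaged forms for 6 genes. The ibufenac minus ibuprofen value was higher in the probe form for TRIB3 (by 0.50 ± 0.08, adjusted p = 0.000601, edgeR). It was lower there for TENT5C (-0.65 ± 0.13), FZD4 (-0.52 ± 0.11), WNT5A (-0.46 ± 0.10), IDI1 (-0.36 ± 0.07) and ADGRL2 (-0.33 ± 0.07), each at adjusted p = 0.0489.

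Of the 12 genes fixed in advance, 8 had arm effects that differed between times. The edgeR adjusted p was 1.02e-06 for HMOX1, 0.000382 for GCLM, 7.09e-05 for TXNRD1 and 5.83e-10 for SLC7A11, which protect against oxidants. It was 1.75e-13 for TRIB3, 2.98e-07 for DDIT3, 4.11e-07 for the cell cycle inhibitor CDKN1A and 8.25e-06 for GDF15. Values at single times are in the results above for HMOX1, TRIB3, DDIT3 and GDF15. CDKN1A rose at 6 h with the ibufenac probe (0.60 ± 0.08, adjusted p = 9.93e-07) and was lower at 18 h (-0.31 ± 0.08, adjusted p = 0.0304).

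The first pattern weighed is the set of list shifts against DMSO. Averaged over the 4 photocaged and probe arms the ATF4 score was higher by 0.28 (95% interval 0.24 to 0.32, exact permutation p = 0.00012), and it was 0.31 (0.28 to 0.35) with GC and length trends removed and 0.27 (0.24 to 0.30) with the share of abundant small noncoding RNAs as a covariate. The NRF2 score in the photocaged arms was higher by 0.27 (exact permutation p = 3.4e-06), and 0.27 (0.22 to 0.32) and 0.27 (0.21 to 0.32) after the same corrections. The hypoxia score was lower, at -0.37 (exact permutation p = 1.1e-06), and stayed at -0.37 (-0.49 to -0.25) after each of them. These values argue against either technical trend as the whole cause. The corrections keep DMSO 18 h replicate 3, on which the hypoxia fall at 18 h largely rests in all of these arms but photocaged ibufenac. The labels do not say which arms went through washes and light, so a difference in handling between drug arms and DMSO stays open for all 3 lists. For the hypoxia list the smaller exact permutation p between the drugs was 0.0395, over 2 comparisons, so handling shared by both drugs cannot be told apart from a drug effect there.

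The second pattern is the higher ATF4 score with ibufenac than with ibuprofen. It was 0.12 (95% interval 0.06 to 0.17) in the photocaged form and 0.27 (0.21 to 0.32) in the probe form. No technical or biological explanation of this difference was tested, and release and loading of the compounds were not measured here.

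The third pattern is the count of 4573 genes between the probes at 6 h against 0 at 18 h. It was 2534 with GC and length trends removed, and at least 3171 when any one of the 6 libraries was left out, so neither a GC or length trend nor one library accounts for it alone. With the small noncoding RNA share as a covariate it was 1411. That share differs between the 2 groups themselves, so a library preparation difference and a drug difference cannot be told apart for the other genes.

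Other splits of the same libraries were fitted to see how often as many genes appear. Against DMSO over the 3 times, only the real split of 100 gave as many genes in the photocaged and probe arms, the smallest share possible here. Real and highest other counts were 591 and 56 for photocaged ibuprofen and 1211 and 231 for photocaged ibufenac. They were 2195 and 876 for the ibuprofen probe and 1983 and 1256 for the ibufenac probe. For the boluses the real count was 0 (highest other 1245 for ibuprofen and 1 for ibufenac), so all 100 of 100 splits necessarily gave as many and the splits decide nothing about the genes called there. These fits hold 18 libraries, so the real counts differ from those of all 63. The same holds between the drugs as bolus (real 0, highest other 2, 100 of 100). For the photocaged form it was 2 of 100 (real 2, highest other 675), and for the probe form 3 of 100 (766, 1894). Between the forms it was 4 of 100 for ibuprofen (33, 777) and 1 of 100 for ibufenac (249, 56). For the interaction it was 1 of 25 (4410, 1). In these last 5 the share was under 0.05, unadjusted for the number of split tests, and 1 of 25 is the smallest possible for the interaction. The splits treat libraries of a time as exchangeable, so with a structure among them they do not exclude chance. Splits with 1245, 675, 777 and 1894 genes lie well above the real counts and may reflect a structure among the libraries beyond the arms. Labels were drawn separately at each time, so a split can also keep the arms at 1 time. Where effects differ between times, as between the probes, such a split can exceed the real count. Which splits gave these counts was not examined.

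At single times the 6 libraries allow 10 splits, too few for a share under 0.05. Given as the number of splits with as many genes, the real count and the highest other, the values at 6, 12 and 18 h follow. The ibuprofen bolus had 1 (10, 0), 10 (0, 56) and 5 (1, 1), and the ibufenac bolus 10 (0, 1), 1 (38, 2) and 10 (0, 0). Photocaged ibuprofen had 1 (137, 106), 1 (729, 1) and 10 (0, 1), and photocaged ibufenac 2 (66, 755), 1 (1686, 0) and 1 (1, 0). The ibuprofen probe had 1 (2352, 1), 1 (2108, 4) and 1 (282, 0), and the ibufenac probe 1 (2228, 0), 1 (191, 2) and 2 (6, 6). Between drugs the bolus had 10 (0, 0), 10 (0, 1) and 1 (1, 0), the photocaged form 1 (3, 1), 1 (11, 4) and 4 (1, 8), and the probe form 1 (3737, 0), 1 (485, 0) and 1 (2, 0). The split with 755 genes may reflect a structure among the libraries, which was not tested.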

How the results depend on the processing

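Removing GC and length trends and leaving out both libraries that stand apart were chosen after seeing the data; the other alternatives were set out beforehand. A count is called moved when it changes by over 1.5 times. Where no cause is named, the cause was not tested.

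As reported, the counts are these. In the report the ibuprofen bolus gave 5 over the times, 0 at 6 h, 2 at 12 h and 14 at 18 h, and the ibufenac bolus gave 2 over the times, 5 at 6 h, 0 at 12 h and 973 at 18 h. Photocaged ibuprofen gave 829 over the times, 192 at 6 h, 131 at 12 h and 428 at 18 h, and photocaged ibufenac gave 1450 over the times, 587 at 6 h, 306 at 12 h and 553 at 18 h. In the report the ibuprofen probe gave 1631 over the times, 2213 at 6 h, 381 at 12 h and 344 at 18 h, and the ibufenac probe gave 2549 over the times, 2466 at 6 h, 872 at 12 h and 521 at 18 h. The drugs as bolus gave 0 over the times, 446 at 6 h, 7 at 12 h and 0 at 18 h, and the photocaged drugs gave 7 over the times, 0 at 6 h, 0 at 12 h and 0 at 18 h. In the report the drugs as probe gave 546 over the times, 4573 at 6 h, 372 at 12 h and 0 at 18 h, and the ibuprofen forms gave 19 over the times. The ibufenac forms gave 519 over the times.

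Of 39 counts of called genes DESeq2 kept 12 within that range and moved 27, each upward. In DESeq2 the ibuprofen bolus gave 38 over the times, 2 at 6 h, 10 at 12 h and 65 at 18 h, and the ibufenac bolus gave 26 over the times, 33 at 6 h and 6 at 12 h. Photocaged ibuprofen gave 299 at 6 h and 345 at 12 h, and photocaged ibufenac gave 573 at 12 h and 1016 at 18 h. In DESeq2 the ibuprofen probe gave 789 at 12 h and 740 at 18 h, and the drugs as bolus gave 12 over the times, 42 at 12 h and 4 at 18 h. The photocaged drugs gave 18 over the times, 6 at 6 h, 1 at 12 h and 2 at 18 h, and the drugs as probe gave 909 over the times and 11 at 18 h. In DESeq2 the ibuprofen forms gave 92 over the times. The count was 1678 for ibufenac bolus versus DMSO, 18 h, 938 for ibuprofen photocaged versus DMSO, 18 h, 985 for ibufenac versus ibuprofen, bolus, 6 h and 901 for ibufenac versus ibuprofen, probe, 12 h.

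Without the low-count filter 12 counts stayed and 27 moved upward; by construction more genes near 0 counts enter the tests. Unfiltered, the ibuprofen bolus gave 436 over the times, 151 at 12 h and 98 at 18 h, and the ibufenac bolus gave 194 over the times, 193 at 6 h and 298 at 12 h. Photocaged ibuprofen gave 343 at 6 h and 664 at 12 h, and the ibuprofen probe gave 971 at 12 h and 1247 at 18 h. Unfiltered, the drugs as bolus gave 111 over the times and 585 at 12 h, and the photocaged drugs gave 89 over the times, 76 at 6 h, 80 at 12 h and 53 at 18 h. The drugs as probe gave 1291 over the times, 1474 at 12 h and 201 at 18 h, and the ibuprofen forms gave 270 over the times. The count was 977 for ibuprofen bolus versus DMSO, 6 h, 1710 for ibufenac bolus versus DMSO, 18 h, 1375 for ibuprofen photocaged versus DMSO, 18 h, 886 for ibufenac photocaged versus DMSO, 12 h, 1343 for ibufenac photocaged versus DMSO, 18 h, 1347 for ibufenac versus ibuprofen, bolus, 6 h and 1124 for ibufenac versus ibuprofen, bolus, 18 h.

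Residuals of the 63 library pairs with the same replicate number at each time had mean correlations of 0.04 at 6 h, -0.004 at 12 h and 0.001 at 18 h, and 23, 13 and 21 of them were over 0.1, so the numbers were not used as pairs. With a replicate block 6 results moved, 4 upward and 2 downward. With the block the ibuprofen bolus gave 9 over the times, 0 at 12 h and 22 at 18 h, and the drugs as bolus gave 702 at 6 h, 1 at 12 h and 1 at 18 h. Under RLE factors 2 results moved, to 7 for the ibuprofen bolus at 18 h and to 1 for the ibufenac bolus at 6 h. The camera tests went from 101 to 32 calls with an estimated correlation.

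Removing GC and length trends moved 14 results, 9 upward and 5 downward. Without the trends the ibufenac bolus gave 8 over the times and 312 at 18 h, and the ibuprofen bolus gave 5 at 12 h. Photocaged ibuprofen gave 353 at 6 h and 258 at 12 h, and photocaged ibufenac gave 545 at 12 h. Without the trends the ibuprofen probe gave 1106 at 6 h, and the ibufenac probe gave 1326 at 12 h. The drugs as bolus gave 121 at 6 h and 1 at 12 h, and the photocaged drugs gave 1 at 12 h. Without the trends the drugs as probe gave 2534 at 6 h, and the ibuprofen forms gave 54 over the times. The count was 887 for ibufenac photocaged versus DMSO, 6 h.

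Leaving out both libraries that stand apart, ibufenac bolus replicate 3 at 6 h and at 18 h, moved 14 results, 12 upward and 2 downward. Without both libraries the ibuprofen bolus gave 8 at 12 h, and the ibufenac bolus gave 0 at 6 h and 86 at 18 h. Photocaged ibuprofen gave 252 at 12 h and 835 at 18 h, and photocaged ibufenac gave 483 at 12 h. Without both libraries the ibuprofen probe gave 714 at 12 h and 608 at 18 h, and the drugs as bolus gave 2 over the times and 31 at 12 h. The photocaged drugs gave 1 at 12 h, and the drugs as probe gave 781 at 12 h. Without both libraries the ibuprofen forms gave 34 over the times. The count was 887 for ibufenac photocaged versus DMSO, 18 h.

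Leaving out each library in turn gave ranges, from fits with fewer samples. Across these fits the ibuprofen bolus gave 0 to 76 over the times, 0 to 182 at 12 h and 0 to 109 at 18 h, and the ibufenac bolus gave 2 to 14 over the times, 0 to 181 at 6 h, 0 to 1 at 12 h and 54 to 1736 at 18 h. Photocaged ibuprofen gave 533 to 851 over the times, 38 to 100 at 6 h, 29 to 78 at 12 h and 48 to 435 at 18 h, and the ibuprofen probe gave 1005 to 1828 over the times, 424 to 2481 at 6 h, 72 to 326 at 12 h and 65 to 349 at 18 h. Across these fits photocaged ibufenac gave 247 to 835 at 6 h, 70 to 195 at 12 h and 105 to 611 at 18 h, and the ibufenac probe gave 1493 to 2228 at 6 h, 469 to 670 at 12 h and 220 to 529 at 18 h. The drugs as bolus gave 0 to 2 over the times, 5 to 777 at 6 h and 0 to 520 at 12 h, and the photocaged drugs gave 2 to 8 over the times, 0 to 1 at 6 h, 0 to 1 at 12 h and 0 to 1 at 18 h. Across these fits the drugs as probe gave 334 to 727 over the times and 83 to 867 at 12 h, and the ibuprofen forms gave 14 to 41 over the times. The ibufenac forms gave 304 to 651 over the times. The interaction ranged from 3781 to 5023, and photocaged ibufenac and the ibufenac probe over the times from 1163 to 1668 and from 2240 to 2554, none of them moved. The difference of the drugs as probe at 6 h ranged from 3171 to 4487.

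The split of higher and lower calls moved by over 10 percentage points for ibuprofen bolus against DMSO over the times from 4 higher and 1 lower to 26 and 12 (DESeq2), ibufenac bolus against DMSO over the times from 0 higher and 2 lower to 17 and 9 (DESeq2), ibuprofen bolus against DMSO, 12 h from 2 higher and 0 lower to 7 and 3 (DESeq2), ibufenac bolus against DMSO, 6 h from 1 higher and 4 lower to 20 and 13 (DESeq2). The same was seen for ibufenac bolus against DMSO, 6 h from 1 higher and 4 lower to 1 and 0 (RLE), ibufenac against ibuprofen, bolus, 12 h from 2 higher and 5 lower to 19 and 23 (DESeq2), ibufenac against ibuprofen, probe over the times from 219 higher and 327 lower to 468 and 441 (DESeq2), ibufenac against ibuprofen, probe, 12 h from 166 higher and 206 lower to 234 and 189 (RLE).

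No named value that was called in either fit changed direction under the alternatives that use all libraries. Changes of sign in values called in neither fit were not counted, here or below. The side of the threshold was kept by 549 of 579 (1 lost, 29 gained) in DESeq2, 591 of 597 (1 lost, 5 gained) with RLE factors and 512 of 597 (26 lost, 59 gained) without the filter. With the replicate block it was 583 of 597 (6 lost, 8 gained), without the trends 562 of 597 (20 lost, 15 gained), without both libraries 580 of 597 (1 lost, 16 gained), and with each library left out 10079 of 10746 (592 lost, 74 gained), with 1 reversed. That 1 was CTBP2P10, a pseudogene, which went from -2.48 with the ibufenac probe to 0.15 (adjusted p 0.907) without DMSO 6 h replicate 2, the only DMSO library at 6 h with counts of it. With each library left out, CTBP2P10 in ibufenac probe versus DMSO, mean of 3 times, ran from -3.55 to 0.15. Single times have 3 libraries per arm: in simulated data for photocaged ibufenac 68% of 1.5-fold changes were found at 6 h and 94% over the times. At the depth of these libraries 19352 of 58336 genes passed the count filter, and the others were not tested. Depth itself was not varied.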

Other observations

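The lists of aminoacyl-tRNA synthetases, amino acid transporters, iron handling, retinoic acid targets and YAP targets were chosen after the results were seen; their tests were set out before they were run.

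Genes for charging transfer RNAs rose in 3 of the 4 photocaged and probe arms, and genes for importing amino acids passed in both ibufenac arms. Of 18 cytosolic aminoacyl-tRNA synthetases 8 rose with photocaged ibufenac, 8 rose and 2 fell with the ibuprofen probe, and 11 rose and 1 fell with the ibufenac probe. With an estimated correlation camera gave adjusted p = 0.0066, 0.03 and 0.000388, and 0.403 for photocaged ibuprofen, where 2 rose and 1 fell. Of 10 amino acid transporters outside the ATF4 list 5 rose and 1 fell with photocaged ibufenac and 6 rose and 1 fell with the ibufenac probe (adjusted p = 0.000817 and 0.000388 with an estimated correlation). With photocaged ibuprofen 2 rose and with the ibuprofen probe 3 rose and 1 fell, where the list passed at the preset correlation (adjusted p = 0.017 and 0.033) but not with an estimated correlation (0.0757 and 0.115). Iron handling genes, a list that shares HMOX1, FTL and FTH1 with the NRF2 list, rose in both photocaged arms, 2 and 4 of 10 (adjusted p = 0.00386 and 0.00194 with an estimated correlation), and were lower in the probe form than in the photocaged form, 3 of 10 with each drug (0.000241 and 0.000117). Both called members with photocaged ibuprofen, and 3 of the 4 with photocaged ibufenac, belong to the NRF2 list, so this result overlaps the NRF2 result.

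A candidate explanation of the ATF4 rise is a general amino acid response, which would raise synthetases as well. Their score was higher by 0.085 (95% interval 0.062 to 0.108, exact permutation p = 0.0043) over the 4 photocaged and probe arms. An interval with an upper limit under 0.05 would have counted against it. It cannot separate an amino acid response from other causes of ATF4 activity, and photocaged ibuprofen alone did not pass in camera.

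The fall of RARB in the photocaged arms may reflect lower retinoic acid signalling, since RARB is itself a retinoic acid target. The other 19 retinoic acid targets had a lower score over those arms together (-0.131, 95% interval -0.243 to -0.019, exact permutation p = 0.0048). By arm it was -0.146 (-0.276 to -0.016) with ibuprofen and -0.116 (-0.246 to 0.013) with ibufenac, where the interval spanned 0. In each of these arms 0 of the 19 were called. Camera did not pass for either photocaged arm (adjusted p = 0.283 for each with an estimated correlation). For the ibufenac probe 4 of the 19 fell, MEIS1, MEIS2, HOXA5 and HOXB4, at adjusted p = 0.0515 with an estimated correlation. The list was lower with the ibufenac probe than with the ibuprofen probe (adjusted p = 0.0304 with an estimated correlation), with MEIS1 and MEIS2 called. The 17 YAP targets passed in none of the 11 comparisons.

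The share of counts in 14 abundant small noncoding RNA genes ran from 12.3% to 28.7% between libraries. It was 26.1% ± 0.5 in DMSO and 19.4% ± 3 with the ibufenac bolus at 18 h (SD, n = 3), the comparison with 973 called genes, and 69 were called with the share as a covariate. Over the 3 times the covariate raised the counts against DMSO to 1611 and 1828 for photocaged ibuprofen and ibufenac and to 2765 and 3223 for the probes, and left 5 and 2 for the boluses. At single times it went both ways: photocaged ibuprofen went from 192 to 417 at 6 h, from 131 to 65 at 12 h and from 428 to 206 at 18 h. Photocaged ibufenac went from 587 to 912 at 6 h and from 553 to 209 at 18 h, and the ibufenac probe from 872 to 1450 at 12 h.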
